A study of Mus musculus with 2 samples.

How the data were processed

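RNA sequencing libraries were made from leukaemia cells sorted from the spleens of leukaemic recipient mice, with 1 library from untreated mice and 1 library from mice given doxycycline (Dox) for 3 days. The authors' deposited tables hold counts, that is whole numbers of reads per gene, with no normalization. Per the submitters' processing notes, the tools named are CASAVA 1.8.2 and featureCounts, and the genome build named is mm10. The aligner, the version of featureCounts, the gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The series' design text speaks of 3 mice per group and of 2 sequencing runs of each RNA, while the deposited count table has 1 column per group. How mice and runs were combined is not given in the sources used here, so no replicate spread could be computed. The values in the series table and in the separate file of each library were compared, and 0 values differed.

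The table lists 27179 genes by Entrez Gene number. Gene symbols and positions were taken from a RefSeq gene table of GRCm38.p6, the assembly behind mm10, which gave 25275 symbols, and from GENCODE, which gave 18 more. The remaining 1886 genes had no symbol here and held 0.805% of the untreated counts and 0.695% of the Dox counts. They stayed in all counts of genes and were not named. Since the treatment of shared reads is not given, values of genes with near-identical copies or many pseudogenes are uncertain, among them the Gimap, Schlafen and HIN-200 families, the granzymes, Gapdh and the ribosomal protein genes. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart.

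Counts were scaled with the trimmed mean of M values (TMM) of edgeR 4.0.16 in R 4.3.3. The TMM factors were 1.02 for the untreated library and 0.984 for the Dox library, and CPM in the text is taken over the TMM-scaled library size. Log2 ratios of Dox over untreated were computed with a prior count of 2, scaled to each library's size, which pulls the ratios of low genes towards 0. Folds in the text are these ratios on the linear scale. Each ratio has an exact 95% interval (Clopper-Pearson, on the share of a gene's counts that fell in the Dox library, without the prior count). Such intervals, and the limit of 3 counts that a count of 0 allows, cover counting error only and hold no spread between mice. With 1 library per group no test was run and no p-value is given, and the differences have no replicate check.

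A size rule fixed before the data were examined took genes with a ratio of at least 2-fold and at least 5 CPM in the higher library. The rule for named genes, fixed at the same time, took the Ikaros family and the 15 largest ratios in each direction among genes past the 5 CPM minimum, leaving out Gm, Rik and LOC names. It also took up to 4 members of each gene list with the largest absolute ratio and at least 5 CPM in the higher library, and the 5 largest ratios in each direction among genes with over 1000 counts in both libraries. Other genes named in the text, mostly further list members, were chosen after their values were seen. Some single-gene values are not reported here.

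The 35 gene lists were also written before the data were examined, from general knowledge of T cell biology and of the cell types a spleen sort could hold. A list member counted as measured with at least 1 CPM in the mean of both libraries. For each list with enough measured members, the median log2 ratio was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile of the median among these describes these libraries and is not a test of the treatment.

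The size rule and the counting intervals were tested on simulated data. Counts were drawn for the real genes at the real depths, with 200 of 27179 genes changed. The draws held counting error only, so the rates below do not cover differences between mice, sorts or library preparations. The size rule recovered 99% of genes changed 3-fold and 100% of those changed 6-fold, and it called 0% of those changed 1.5-fold. Among 9821 unchanged genes past the CPM minimum, 0 met the rule. The counting intervals held the true ratio for 95.3% of 10019 genes.

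Alternatives tried were DESeq2 1.42.0 size factors, total counts, prior counts of 0.5 and 5, CPM minimums of 1 and 20 and none, the size rule applied to the interval bound nearest to 0, and list members with at least 5 CPM. Thinning the Dox counts to the untreated total and removing the trend of the ratio with gene length were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.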

Results

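Transcripts were measured by RNA sequencing in ALL65, a primary mouse T cell acute lymphoblastic leukaemia (T-ALL). The leukaemia carries a tetracycline-controlled short hairpin RNA against Ikaros, a zinc finger transcription factor of lymphoid cells encoded by Ikzf1, and the hairpin is linked to green fluorescent protein (GFP). Dox switches the hairpin off, and Ikaros made from the cells' own gene returns. GFP-high cells of untreated mice and GFP-mid cells of mice given Dox for 3 days were sorted from the spleen, so that the groups differ in the sort gate as well as in treatment. The comparison asks how the transcripts of established leukaemia cells differ once Ikaros is restored.

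Each group had 1 library, so no value below has a replicate error and the differences have no replicate check. The untreated library held 7477988 counts and the Dox library 14457475 counts over 27179 listed genes. A count was recorded for 14398 genes in the untreated library and for 15091 in the Dox library, and a count of 0 allows up to 0.395 CPM and 0.211 CPM. The most abundant gene took 0.813% of the untreated counts and 0.896% of the Dox counts. Bounds given beside ratios are exact 95% counting intervals, which reached a median of 0.19 on the log2 scale to either side over the genes past the 5 CPM minimum.

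Ikzf1 (Entrez Gene 22778, chromosome 11 from 11684962 to 11772930 in mm10), the gene the hairpin targets, was 5.55-fold higher in the Dox library. Its level was 262 CPM without Dox and 1455 CPM with Dox, from 1992 and 20702 counts, and the log2 ratio was 2.47 (2.41 to 2.54). Of the other family members, Ikzf2, which encodes Helios, was 1.72-fold higher with a log2 ratio of 0.78 (0.71 to 0.85). Ikzf3, which encodes Aiolos, had a log2 ratio of -0.13 (-0.21 to -0.05), Ikzf4 of -0.04 (-0.54 to 0.46) and Ikzf5 of 0.05 (-0.23 to 0.34). The median of the 5 family members was 0.05, at percentile 62.0 of the matched random lists.

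Most transcripts stood at similar levels in both libraries. Of 10113 genes with at least 5 CPM in the higher library, 8853 (87.5%) lay within 1.5-fold. At least 2-fold higher with Dox were 223 genes (2.21%) and at least 2-fold lower were 227 (2.24%). Ratios of at least 4-fold were found for 30 genes higher and 51 lower, and of at least 8-fold for 1 higher and 15 lower. The log2 CPM of both libraries had a Pearson r of 0.964 across genes, which are not independent replicates. With a bound of the counting interval, in place of the ratio itself, past 2-fold, the counts were 115 higher and 141 lower.

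**Figure D1:**
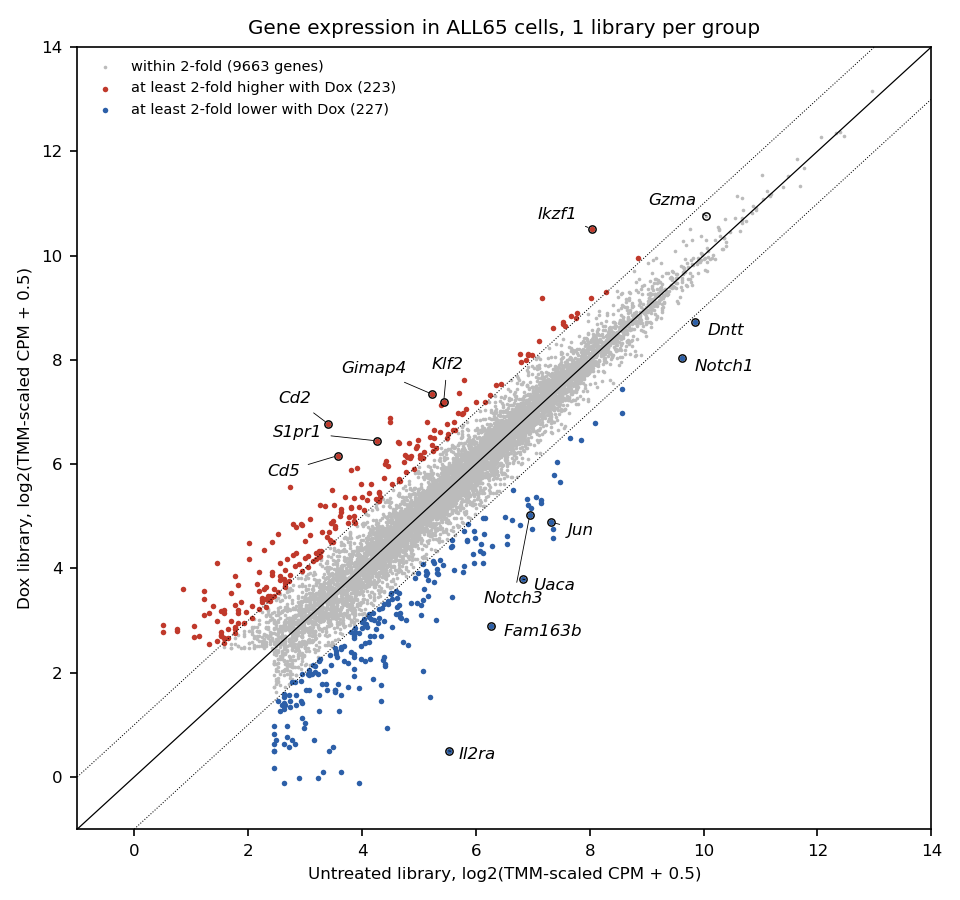
Each point is a gene with at least 5 CPM in the higher library, with the untreated library on the x axis and the Dox library on the y axis, both as log2 of TMM-scaled CPM plus 0.5. Red points are the 223 genes at least 2-fold higher with Dox and blue points the 227 at least 2-fold lower, dotted lines mark 2-fold, and Ikzf1 stands well above the diagonal while Il2ra is the farthest below it.

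The gene with the largest ratio was Cd2, an adhesion receptor of T cells, 10.5-fold higher with Dox at 10.1 and 109 CPM and a log2 ratio of 3.40 (3.09 to 3.77). It was followed by Bcl3, an IkB family protein, at 2.97 (2.22 to 4.23), and by Gimap3 at 2.89 (2.49 to 3.38) and Gimap7 at 2.81 (2.20 to 3.71), GTPases of immune cells. Nr4a3, a nuclear receptor induced by T cell receptor signals, had a log2 ratio of 2.71 (1.84 to 4.28). Cd5, a surface receptor that dampens T cell receptor signals, stood at 2.62 (2.32 to 2.97). The remaining genes of the 15 largest were Scel at 2.57, Mcoln3 at 2.56, Arsb at 2.51, Gimap8 at 2.40, Gpr171 at 2.35, Gramd3 at 2.33, Ankrd55 at 2.31 and Slc15a1 at 2.28, beside Ikzf1. Bcl3, Nr4a3, Scel, Arsb, Gpr171, Ankrd55 and Slc15a1 rested on under 15 untreated counts each.

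In the other direction, Il2ra, which encodes the alpha chain of the interleukin 2 receptor (CD25), was 41.5-fold lower with Dox. It had 345 untreated and 13 Dox counts, 45.4 and 0.914 CPM, and a log2 ratio of -5.38 (-6.56 to -4.84). Lmcd1 followed at -4.65 (-6.63 to -3.99), the imprinted non-coding RNA H19 at -4.01 (-5.65 to -3.36) and Ifi202b, an interferon-inducible HIN-200 gene, at -3.82 (-4.48 to -3.40). Next were Rgma at -3.75, the HIN-200 gene Ifi211 at -3.74 and the axon guidance gene Slit1 at -3.70. Fam163b, at 76.2 and 6.96 CPM, had a ratio of -3.42 (-3.78 to -3.14), and Uaca, at 113 and 13.4 CPM, one of -3.06 (-3.31 to -2.85). The remaining genes were Hfe at -3.41 (-5.21 to -2.68), P3h3 at -3.27 (-5.27 to -2.51), Sertad4 at -3.25, Scn4b at -3.23, Zfp111 at -3.14 and Wdfy4 at -3.03. Il2ra, Lmcd1, H19, Ifi211, Slit1, Hfe, P3h3, Sertad4 and Scn4b rested on under 15 Dox counts each.

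Among genes with over 1000 counts in both libraries, the most precisely measured, the largest ratios after Ikzf1 were those of Myo6 at 2.03, Cd8b1 at 1.27, Shisa5 at 1.26 and Anxa6 at 1.20. The lowest were those of Notch1 at -1.60, Tmed5 at -1.58, Col27a1 at -1.38, H1f0 at -1.31 and Ybx3 at -1.16.

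Genes of the Notch pathway and its targets, a signal on which T-ALL cells commonly depend, stood lower with Dox. Of 14 measured members, 4 were at least 2-fold lower and 0 at least 2-fold higher, and the median log2 ratio of -0.43 lay below all 10000 matched random lists. Notch1 was 3.02-fold lower at 789 and 261 CPM, with a log2 ratio of -1.60 (-1.66 to -1.54). Notch3 was 3.83-fold lower at 123 and 32.0 CPM, with a ratio of -1.94 (-2.11 to -1.78), and Heyl, a transcriptional repressor induced by Notch, had one of -1.39 (-2.15 to -0.78). The other member past 2-fold was Il2ra. Ratios were smaller for Myc at -0.72 (-0.79 to -0.65) and Hes1 at -0.67 (-0.85 to -0.50). Not all members stood lower, since Dtx1 had a ratio of -0.01 (-0.11 to 0.08) and Trib2 one of 0.67 (0.58 to 0.75).

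Genes of immature and double-positive thymocytes, the stage at which CD4 and CD8 are both present, went in both directions. Of 15 measured members, 2 were at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.35 at percentile 99.98. The recombinase gene Rag1 was 2.90-fold lower at 90.5 and 31.1 CPM, with a log2 ratio of -1.54 (-1.72 to -1.37). Rag2, at 19 and 10 counts, had a ratio of -1.60 (-3.10 to -0.65), and Dntt, which encodes terminal deoxynucleotidyl transferase, one of -1.12 (-1.17 to -1.07). The co-receptor genes stood higher, with Cd8b1 at 1.27 (1.18 to 1.36), Cd4 at 0.83 (0.67 to 0.99) and Cd8a at 0.80 (0.75 to 0.85). The chemokine receptor gene Ccr9 was 2.23-fold higher, at 1.15 (1.08 to 1.23).

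The T cell receptor signalling list had 4 of 21 members at least 2-fold higher and 0 at least 2-fold lower, and its median of 0.45 lay above all random lists. Beside Cd2 and Cd5 these were Cd6, a receptor related to Cd5, at 1.67 (1.52 to 1.83) and the kinase gene Prkcq at 1.15 (1.07 to 1.24). Genes of the receptor complex went in both directions, with Cd247, the zeta chain, at 0.78 (0.70 to 0.85), Cd3d at -0.25 (-0.31 to -0.18) and Cd3e at -0.09 (-0.17 to -0.01). The kinase gene Lck stood at -0.21 (-0.25 to -0.18).

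Genes of mature T cell migration and quiescence had the largest list median among the pathway and stage lists, 1.003, above all random lists. Of 16 members, 8 were at least 2-fold higher, 11 at least 1.5-fold higher and 0 at least 1.5-fold lower. S1pr1, the receptor by which lymphocytes leave thymus and lymph nodes, was 4.57-fold higher at 18.8 and 86.6 CPM, with a log2 ratio of 2.19 (1.95 to 2.46). Klf2, a transcription factor that activates S1pr1, stood at 1.76 (1.59 to 1.94), the antiproliferative gene Tob1 at 1.88 (1.55 to 2.27) and Ms4a4b at 1.78 (1.56 to 2.01). The chemokine receptor gene Ccr7 had a ratio of 1.04 (0.87 to 1.21), while Il7r, at 44 and 93 counts, had one of 0.17 (-0.36 to 0.73). Xist, a non-coding RNA of the inactive X chromosome in female cells, had 0 counts in the untreated library and 11 in the Dox library. Y-linked genes were present in both libraries, with Ddx3y at 136 and 140 CPM, and the 4 measured sex-linked genes had a median of 0.04 at percentile 54.8.

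**Figure D2:**
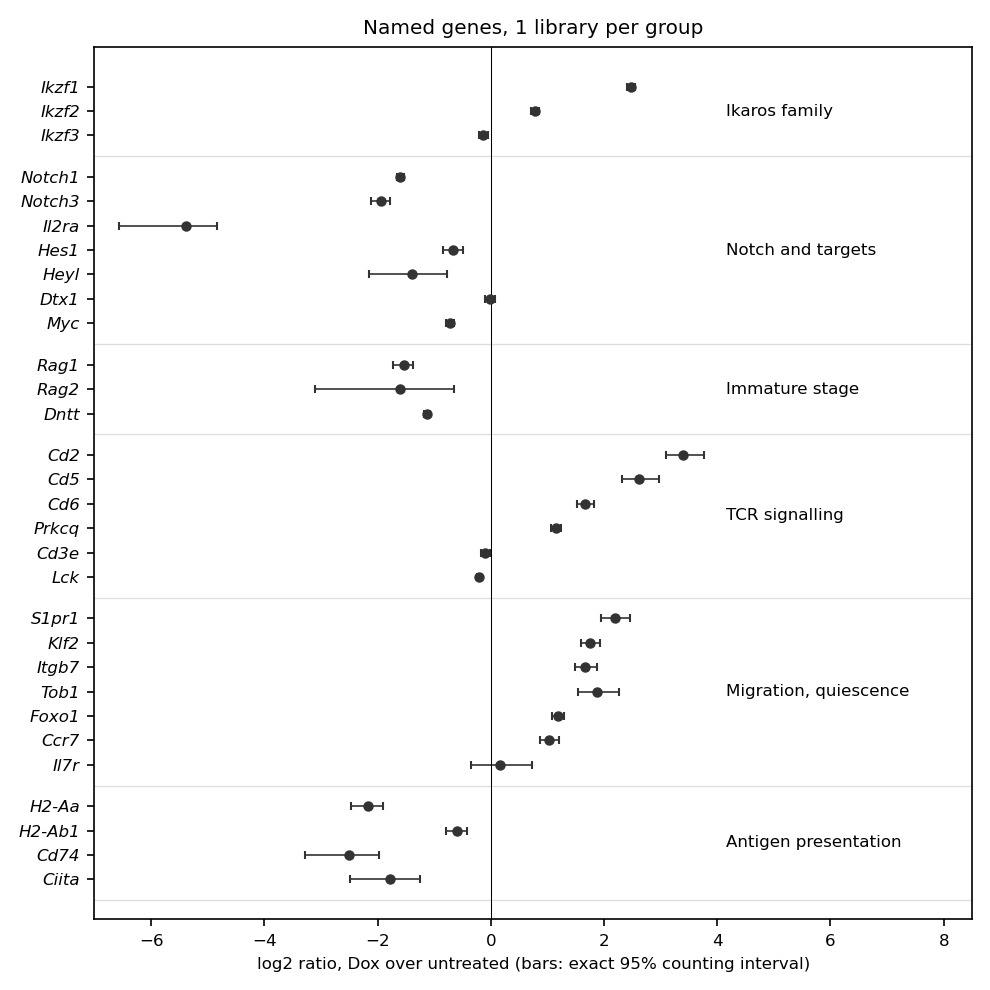
Points are the log2 ratios of Dox over untreated for named genes, grouped by gene list, and bars are exact 95% counting intervals from 1 library per group. Ikzf1, Cd2, Cd5 and S1pr1 lie above 2, while Il2ra lies below -4 and its bar, from 13 Dox counts, is among the widest.

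The T lineage transcription factors had a median of 0.15 over 16 members, at percentile 95.7. Runx1 and Runx3, related factors of early and of CD8 T cells, stood apart in opposite directions. Runx1 was 2.17-fold lower with a ratio of -1.12 (-1.20 to -1.04) and Runx3 2.11-fold higher with one of 1.07 (0.94 to 1.21). Zbtb7b, a factor of CD4 T cells, had a ratio of 0.83 (0.64 to 1.03). Of the 16 genes listed as stem cell and leukaemia transcription factors, 1 was measured, Kit, which encodes a receptor tyrosine kinase and stood at 2.37 and 3.02 CPM.

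Genes of ribosome biogenesis stood lower with Dox as a group, each by a small amount. All 22 members had a ratio under 0, 2 were at least 1.5-fold lower and 0 at least 2-fold lower, and the median of -0.34 lay below all random lists. Polr1b, a subunit of RNA polymerase I, had a ratio of -0.65 (-0.77 to -0.52), Gnl3 one of -0.62 (-0.70 to -0.54) and nucleolin (Ncl) one of -0.36 (-0.38 to -0.34). The ribosomal protein genes did not share this size, with a median of -0.05 at percentile 8.89.

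The integrated stress response list, genes induced by amino acid shortage and other stress through Atf4, also lay below all random lists, with a median of -0.46. Of 16 members, 2 were at least 2-fold lower and 0 at least 1.5-fold higher. Slc7a5, a transporter of large amino acids, was 1.81-fold lower at 339 and 187 CPM, with a ratio of -0.85 (-0.93 to -0.78). Atf5 stood at -0.75 (-1.05 to -0.47) and Atf4 at -0.45 (-0.56 to -0.34). The members past 2-fold, Trib3 and Chac1, had 29 and 25 untreated counts and 7 and 1 Dox counts. Cholesterol synthesis genes had a median of -0.16 at percentile 2.26, and with a minimum of 5 CPM the percentile was 2.86.

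The S phase and DNA replication list had a median of -0.04 at percentile 11.3, with 0 of 21 members past 2-fold. Genes of G2/M and mitosis stood higher with Dox as a group, each by a small amount, with a median of 0.27 at percentile 99.98. All 20 members had a ratio above 0, but 0 reached 1.5-fold, and the largest ratio was 0.44 (0.41 to 0.47), for Top2a. The glycolysis median was -0.03 at percentile 22.0, with the lactate transporter gene Slc16a3 at 1.97 (1.29 to 2.95) and Hk2 at -0.90 (-1.12 to -0.70). Nuclear genes of oxidative phosphorylation had a median of -0.004 at percentile 29.5, and transcripts of the mitochondrial genome one of 0.19 at percentile 97.4.

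Interferon response genes stood higher with Dox on balance, with exceptions. Of 20 members, 11 were at least 1.5-fold higher and 4 at least 1.5-fold lower, and the median of 0.63 lay above all random lists. Ifi27l2a was 3.98-fold higher with a log2 ratio of 1.99 (1.60 to 2.47), and the interferon regulatory factor Irf7 at 1.39 (1.12 to 1.70) and Ddx58, a sensor of viral RNA, at 1.39 (1.19 to 1.60) were also past 2-fold. Bst2 stood at -0.87 (-1.09 to -0.65) and Oas2 at -0.84 (-1.21 to -0.49). The cytokine and JAK-STAT list had a median of 0.37 at percentile 99.99, with Il4ra at 1.02 (0.61 to 1.497) and Il2rg at 0.82 (0.72 to 0.93).

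Checkpoint and activation markers had a median of 0.64 at percentile 99.97, with 2 of 9 members at least 2-fold higher. These were Egr2 at 2.04 (1.38 to 2.98) and Nr4a1 at 1.49 (1.30 to 1.70), early genes of T cell receptor signalling. The immediate early genes, which also respond to cell handling, had a median of 0.20 at percentile 96.9 over 13 members. Jun was 5.46-fold lower at 160 and 29.1 CPM, with a ratio of -2.45 (-2.62 to -2.29), and Egr1 stood at 0.93 (0.79 to 1.08). Cytotoxic effector and chemokine genes had a median of 0.65 at percentile 99.8 over 8 members, with Gzma, a granzyme abundant in these cells at 1059 and 1739.9 CPM, at 0.72 (0.68 to 0.75) and Eomes at 1.19 (0.71 to 1.77). With no filter on low counts that median was 0, at percentile 50.1.

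Integrin and focal adhesion genes had a median of 0.33 at percentile 99.98, with 3 of 17 members at least 2-fold higher and 3 at least 1.5-fold lower. Itgb3 at 1.30 (1.15 to 1.47), Itgb2 at 1.11 (1.01 to 1.22) and the actin crosslinker gene Flna at 1.11 (1.05 to 1.16) stood higher, and Itga6 at -0.78 (-0.93 to -0.63) lower. The p53 target list had a median of 0.24 at percentile 99.1, and without a filter on low counts a percentile of 88.5. Of its 14 measured members, 4 were at least 1.5-fold higher, among them Trp53inp1 at 1.02 (0.96 to 1.09). Btg2, another of these, also belongs to the mature T cell list. The other 10 lay within 1.5-fold, among them Mdm2 at 0.33 (0.22 to 0.45), Bax at 0.02 (-0.12 to 0.17) and Cdkn1a at -0.46 (-1.65 to 0.65). The Bcl2 family and apoptosis list stood at 0.12, percentile 88.9, with the death receptor gene Fas at 1.18 (0.74 to 1.69) and Bcl2l11, which encodes the pro-apoptotic protein BIM, at 0.68 (0.55 to 0.82). The PI3K and mTOR list stood at 0.17, percentile 96.4, with Ddit4 at 1.16 (1.04 to 1.29) and Sesn3 at 1.11 (0.87 to 1.36), both inhibitors of mTOR signalling.

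**Figure D3:**
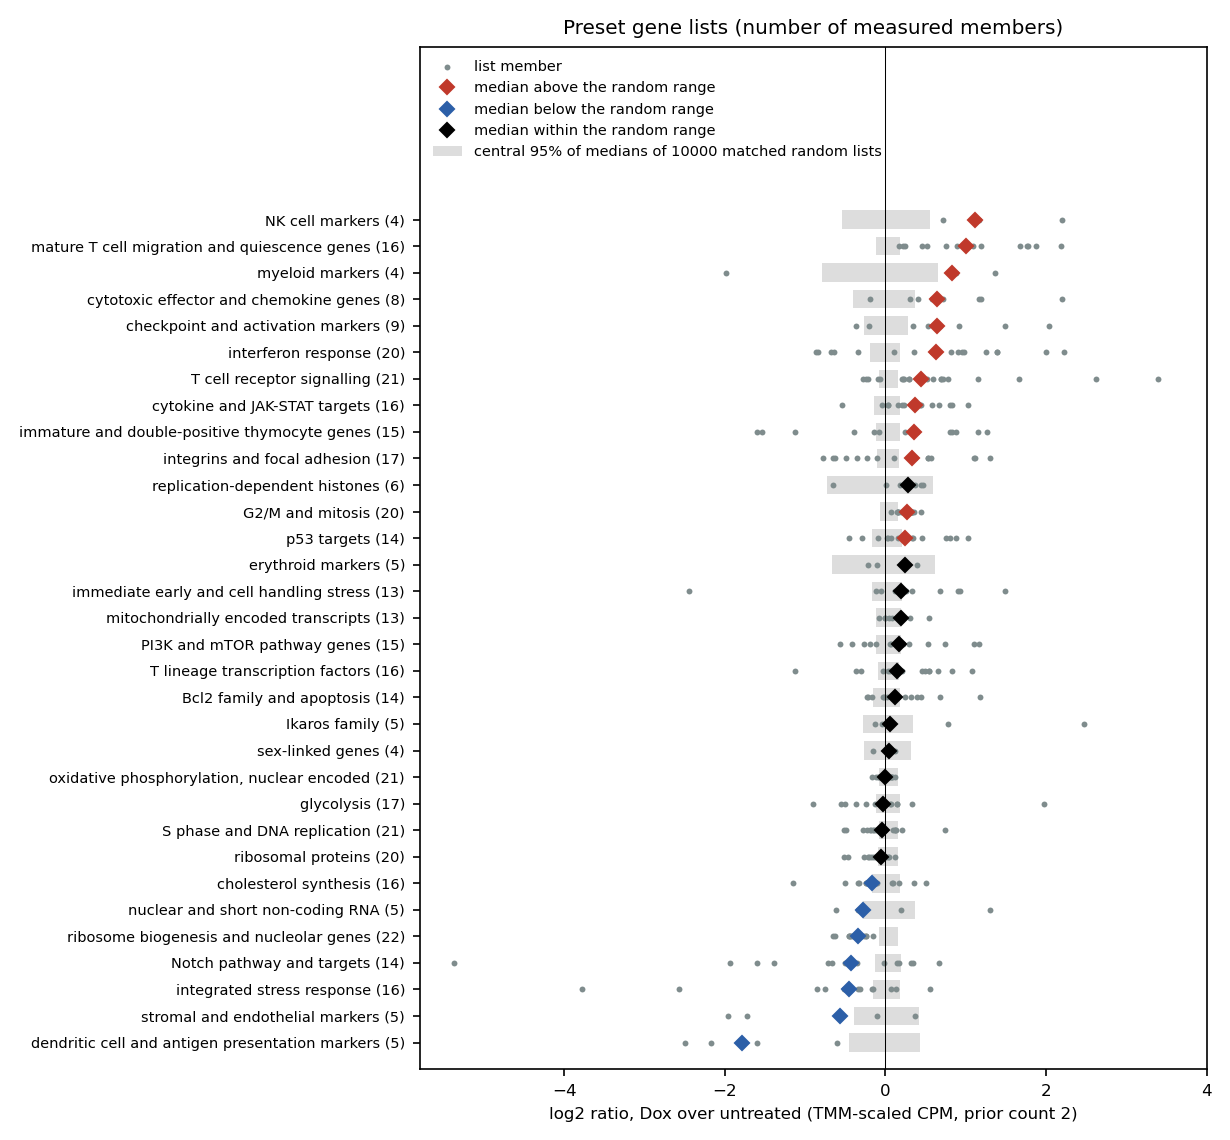
For each gene list with a median, grey dots are the log2 ratios of Dox over untreated of the measured members, the diamond is their median and the grey bar spans the central 95% of the medians of 10000 random lists matched on expression. Of 32 lists, 12 have a median above this range, led by NK cell markers and mature T cell genes, and 7 below it, led by the dendritic cell and antigen presentation list. The NK median rests on 4 measured genes, and the other 8 of the 12 listed were under 1 CPM.

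Markers of other cell types were mostly near or under the detection limit. Of 14 B cell markers 12 were under 1 CPM, and the exceptions were Vpreb3 at 2.76 and 3.59 CPM and Ighm, which T lineage cells can also transcribe, at 401 and 519 CPM. Of 10 megakaryocyte and platelet markers, 1 (Gp1ba) passed 1 CPM, at 1.18 and 1.12 CPM. The 5 measured erythroid markers had a median of 0.24 at percentile 83.3. Of 17 myeloid markers 4 were measured, with a median of 0.83 at percentile 99.0. They moved apart, since Itgam stood at 0.79 (0.39 to 1.23) and Lyz2 at -1.99 (-2.86 to -1.38). Of 12 NK cell markers 8 were under 1 CPM, among them the receptor genes Ncr1, Klrk1 and Klrd1 with 0 counts in both libraries. The 4 measured ones, Gzma, Txk, Prf1 and Nkg7, had a median of 1.12 at percentile 99.94. Txk, a T cell kinase as well, stood at 1.07 (0.91 to 1.25). Prf1 had 3 untreated and 35 Dox counts, and Nkg7 had 9 and 41. Gzma, Prf1 and Nkg7 also belong to the cytotoxic list. The 5 measured stromal and endothelial markers had a median of -0.56 at percentile 0.65, and they too moved apart, with Pdgfrb at -1.72 (-2.04 to -1.45), Col1a2 at -0.56 (-0.67 to -0.45) and Pecam1 at 0.37 (0.27 to 0.47). Without a filter on low counts, the percentiles of the myeloid, NK and stromal lists were 73.5, 49.8 and 42.5.

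The dendritic cell and antigen presentation list had the lowest median of all lists, -1.79, below all random lists. Its 5 measured members all belong to MHC class II presentation, and 4 of them were at least 2-fold lower with Dox. H2-Aa was 4.49-fold lower at 47.4 and 10.4 CPM, with a ratio of -2.17 (-2.47 to -1.91). Cd74, the invariant chain gene, stood at -2.50 (-3.29 to -1.97), the class II transactivator gene Ciita at -1.79 (-2.49 to -1.25), H2-Eb1 at -1.60 (-2.25 to -1.09) and H2-Ab1 at -0.60 (-0.79 to -0.42). The other 7 listed genes, such as Itgax with 1 and 3 counts, were under 1 CPM, and with all 12 genes the median was 0. The myeloid marker Lyz2 was lower alongside these genes, as given above.

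Of the lists that bear on RNA quality, nuclear and short non-coding RNAs had a median of -0.28 over 5 members, just below the central 95% of random lists at percentile 2.47, and at percentile 2.52 with total counts. Gas5 stood at -0.61 (-0.69 to -0.54) and Malat1 at 0.19 (0.11 to 0.27), while Rpph1, with 5 and 27 counts, was at least 2-fold higher at 1.31 (0.13 to 3.26). Replication-dependent histones, most of which lack poly(A) tails, had a median of 0.28 at percentile 85.8 over 6 members, the most abundant of which, H1f2, stood at 6.05 and 6.89 CPM.

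The T cell receptor segments with the most counts were the same in both libraries. Trbv5 took 83.2% of the Trbv counts without Dox (exact 95% interval 82.4% to 84.0%, 7609 of 9144) and 81.2% with Dox (80.7% to 81.8%, 14770 of 18180). The next segment was Trbv13-2 in both, with 7.37% and 7.51%. Among Trav segments, Trav4-4-dv10 took 38.1% (34.6% to 41.7%) and 42.8% (40.9% to 44.7%), and the next segment, Trav14d-3-dv8, took 22.7% and 17.1%.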

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

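The choices named here were made before the data were examined, except thinning and the length correction, which were chosen after seeing the data. The log2 ratio of Ikzf1 lay between 2.43 and 2.47 under every alternative that gave one. The count of genes past the size rule followed the CPM minimum, by construction, since a lower minimum lets in more genes near the floor. It was 407 higher and 440 lower with a minimum of 1 CPM, 129 and 104 with 20 CPM, and 784 and 744 with no filter. With the interval bound past 2-fold it was 115 and 141. It stayed within 1.5 times the main count with DESeq2 size factors (221 higher, 229 lower), total counts (202 and 242), prior counts of 0.5 (227 and 233) and 5 (210 and 222), the length trend removed (215 and 235) and the Dox library thinned to the untreated total (226 and 236). Of the 223 higher and 227 lower genes, 202 and 227 were shared with the total count result and 206 and 214 with the thinned one. Total counts shifted all ratios by -0.05, and DESeq2 size factors by -0.004.

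Among 1064 alternative values of 152 named genes, 1059 differed from the main value by less than the mean reach of its counting interval to either side. Of those with a main ratio of at least 2-fold, 0 reversed in sign, and sign changes of smaller ratios were not counted. Of 284 alternative list medians, 268 lay within the counting spread, and 0 reversed among lists whose main median was outside the central 95% of random lists. Both totals include a setting on each library's own file, whose counts equal the main ones, so its values match by construction. With no filter on low counts, the lists of p53 targets, cytotoxic, myeloid, dendritic, NK and stromal genes were no longer outside the central 95% of random lists, by the construction of a median that then includes genes at or near 0 counts. Cholesterol synthesis and non-coding RNA, close to the limit, also left it under some alternatives, among them the length correction (percentiles 2.91 and 2.88). With the same correction the T lineage factors (97.9) and mitochondrial transcripts (98.4) moved just past it, as the immediate early genes did with a 5 CPM minimum (98.7). No paired analysis was possible because each group has 1 library. For the same reason no mouse could be left out, no run analysed alone, and no edgeR or DESeq2 test run. Depth limits ratios of low genes, whose intervals reached a median of 0.58 on the log2 scale to either side near 5 CPM against 0.13 near 100 CPM.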

Other observations

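The gene families in this part, and the tests on MHC class II genes and mature T cell genes, were chosen after the values had been seen, with marker sums and bounds revised since, while those on counting noise, chromosome copy number and mice or gates were planned. The Gimap genes, GTPases of lymphocyte survival that form a cluster on chromosome 6 (48647186 to 48770851 in mm10), stood higher together. Of 8 measured members 7 were at least 2-fold higher with Dox, with a median log2 ratio of 1.97. The lowest was Gimap9 at 0.67 (0.52 to 0.82), and the most abundant with Dox, Gimap6, stood at 55.0 and 196 CPM, a ratio of 1.83 (1.68 to 1.98). The HIN-200 genes, interferon-inducible DNA sensors in a cluster on chromosome 1 (173349547 to 174031755), divided instead. Ifi208 at 1.24 (0.97 to 1.54), Ifi209 at 1.20 (1.03 to 1.37), Ifi213 and Ifi214 were at least 2-fold higher. Ifi202b, Ifi204 at -1.95 (-2.14 to -1.77), Ifi205, Ifi207 and Ifi211 were at least 2-fold lower, and the genes higher lie side by side at lower coordinates than the genes lower. In the Schlafen cluster on chromosome 11, Slfn5 at 1.65 (1.38 to 1.96) and Slfn8 at 1.35 (1.14 to 1.58) stood against Slfn9 at -1.95 (-2.13 to -1.78). Members of these families resemble one another in sequence, and how shared reads were counted is not given in the sources used here.

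Of 10 amino acid transporter genes, picked by name and not set against random lists, 3 were at least 2-fold lower with Dox, with a median of -0.68. Slc7a5 and Slc7a11 among them also belong to the integrated stress response list, and Slc7a11 went the other way at 0.55 (-0.18 to 1.40). Among the abundant ones, Slc1a5 had a ratio of -0.72 (-0.83 to -0.61), Slc7a1 of -0.64 (-0.74 to -0.55) and Slc3a2 of -0.61 (-0.70 to -0.51). The most abundant, Slc38a1 and Slc38a2, had smaller ratios of -0.20 (-0.25 to -0.14) and -0.29 (-0.36 to -0.23). Those past 2-fold, Slc1a4, Slc38a3 and Slc7a3, had 38, 50 and 15 untreated counts and 9, 15 and 7 Dox counts. Of 12 NF-kB genes 3 were at least 2-fold higher, Bcl3, Nfkbiz at 1.29 (0.95 to 1.67) and Relb at 1.13 (0.76 to 1.56), with a median of 0.44.

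The 450 genes past the 2-fold size rule were first set against counting noise. Libraries drawn from 1 common profile at the real depths gave a mean of 0.49 such genes in 100 draws and at most 2. Nor did a whole chromosome stand apart, since the autosome farthest from 0, chromosome 13, had a median log2 ratio of 0.0327, which argues against gained or lost chromosomes. Differences between mice, or between the GFP-high and GFP-mid gates, cannot be told apart from Ikaros restoration with 1 library per group, and effects of Dox itself on all these genes were not tested.

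For the lower MHC class II genes, a candidate source is fewer B cells, dendritic cells or macrophages of the host in the Dox sort, which a GFP gate should remove. The summed counts of 37 other markers of these cells, Ighm left out, went from 196 to 481, a log2 ratio of 0.39 (0.15 to 0.64), which goes against it. Without Itgam, Cd68 and Vpreb3, which dominate it, the sum gave -0.28 (-0.68 to 0.13), also above a 2-fold fall. The 15 myeloid markers without Itgam and Cd68, at 78 untreated and 91 Dox counts, gave -0.68 (-1.13 to -0.23). Lyz2 among them went from 55 to 24 counts, and the rest of that sum did not fall. Host cells as a source thus stay open through Lyz2. Restored Ikaros acting in the leukaemia cells may also lower these genes, but the ratio of Ciita, -1.79 (-2.49 to -1.25), is part of the pattern and would be lower under either explanation. The design cannot decide between them.

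For the higher mature T cell genes, mature T cells of the host in the GFP-mid gate are a candidate source, which the gate should limit. The Trbv5 share was lower with Dox by a difference of -1.97 percentage points, and Xist went from 0 to 11 counts, both in the direction that other cells would give, while the leading Trav segments moved apart, Trav4-4-dv10 from 38.1% to 42.8% and Trav14d-3-dv8 from 22.7% to 17.1%, and decide nothing. Among genes abundant in mature T cells, Ccr7 and Ltb gained 51.8 and 64.4 CPM, near the 59.8 CPM of Cd5, while Il7r gained 0.748 CPM, which goes against it. The size of any such share was not measured, and it stays open. Ikaros restoration in the leukaemia cells may also raise these genes, but the ratio of S1pr1, 2.19, is itself part of the pattern, and 1 library per group cannot decide.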
